A study of Mus musculus with 6 samples.

How the data were processed

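MicroRNAs (miRNAs) were measured in extracellular vesicles (EVs) collected from the bone of male mice, on 6 single-colour Agilent arrays of mouse miRNAs. Per the labels, 3 arrays carried RNA from young mice of 1 month and 3 carried RNA from aged mice of 16 months. The title of the series speaks of osteocytes, the cells embedded in the bone matrix, whereas the sample labels name bone, and the wording of the sample labels is used here. Per the labels' protocols, RNA was prepared with the SBI SeraMir kit, which amplifies small RNA from vesicles, and was labelled with the dye Cy3 using Agilent's labelling and hybridization kit. The labels number the replicates 1 to 3 in each group and do not say whether they came from separate animals or from pools. The p-values therefore measure only the spread between these samples, which may be technical.

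Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 10.7.1.1, and the intensity of each spot was deposited as a background-subtracted and spatially detrended signal with no scaling between arrays. The mean spot intensity, the local background intensity and Agilent's total signal per miRNA were taken from the same deposited files for alternatives. Other columns used from the deposited files were flags of 0 or 1 per spot or per miRNA for signal well above background, outliers, saturation and detection. The deposited series matrix held intensity values that equalled the processed signal rounded to 3 digits, with a largest relative difference of 0.494% to 0.496% per array. Its column medians were -0.0023, 0.212 and 0.171 for young arrays 1 to 3 and 0.104, 0.5325 and 0.601 for aged arrays 1 to 3. This match settled its linear scale and the absence of centring, and a matrix of single-channel intensities has no direction. The authors' deposited list of differentially enriched miRNAs held a fold change of aged over young, a ratio on a linear scale, for 46 miRNAs. The same deposited list held a p-value per miRNA, and the test, the normalization and the adjustment behind it are not given in the sources used here.

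The array held 56430 non-control spots, 4415 probes and 1881 mouse miRNAs. Spots carrying an outlier flag, 2.13% to 3.13% of spots per array, were left out, and no spot was saturated. The remaining spots of a probe were averaged on the linear scale. A probe was taken as detected on an array when over 50% of its spots were well above background, and a miRNA when its probe was. Each array was divided by its 75th percentile over the 198 probes detected on all arrays, after which signals were raised to a floor of 20.5 and converted to log2, so that the floor lay at 4.36. The floor was the median over the arrays of the lowest scaled signal of a detected probe. A miRNA was represented by its probe with the highest mean over the 6 arrays. For 122 miRNAs several probes detected on at least 3 arrays could be compared. Of these, 0 had probes with opposite changes above 0.5 in size on the log2 scale and 1, miR-483-5p, had probes differing by over 1. Probes detected on fewer arrays were left out of this comparison, so it does not show that all probes of a miRNA changed alike. With the mean of all probes the log2 difference was 1.18 for miR-5128 and 0.67 for miR-6973b-5p, against 2.35 and 1.34 with the chosen probe.

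The 150 miRNAs detected on all 3 arrays of at least 1 group were compared between aged and young with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the package data.table, version 1.17.8, for reading, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 6.69 degrees of freedom including those of the prior. Fold changes were computed on floored values, which can understate or overstate the change of dim miRNAs. The lowest detected scaled signal was below the floor on young array 3 (17.4) and on aged arrays 2 (13.4) and 3 (10.4). Detected aged values below the floor were thus raised to it. For miR-2861 the aged log2 mean was 5.85 with the floor and 5.73 without it. Where a miRNA was not well above background on any array of a group, the fold was given only as a bound, the mean of the bright group over the mean of, per array, the higher of the lowest detected signal and the probe's own signal. Differences computed for such miRNAs entered the fits and the ranges over alternatives at their floored values. Numbers of detected miRNAs were compared by an exact two-sided permutation test over the 10 splits of 3 against 3 arrays, which cannot go below 0.1.

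A total of 23 miRNA lists was fixed before the data were examined, as were the tests, the alternatives and the rule for naming miRNAs. The lists covered markers of erythroid, myeloid, lymphoid, endothelial, muscle, cartilage, liver, neural, epithelial and fibroblast or mesenchymal cells. Others covered miRNAs promoting or inhibiting osteogenesis, promoting adipogenesis or associated with senescence. The remaining lists were the miR-23a cluster, the let-7, miR-29 and miR-30 families, the miR-17 to miR-92a cluster with its paralogs, the miRNAs of the Dlk1-Dio3, Igf2/H19 and Sfmbt2 regions, and all miRNAs numbered from 1900. The 3 lists with at least 3 tested members were tested with camera of limma at its preset correlation of 0.01, with an estimated correlation and with fry as alternatives. The rule named miR-483-5p and miR-2861, which the study is known to have followed up. It also named the 10 largest changes per direction past the threshold, or the 5 smallest p-values of a direction where fewer than 5 passed, and up to 4 tested members of each list. The rule further took the 10 miRNAs with the highest mean signal, and up to 5 per direction detected on all arrays of 1 group and none of the other. It gave 33 miRNAs, and others named were chosen after their values were seen, as is stated beside them.

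Names of overlapping genes came from RefSeq annotation of the assembly GRCm38.p6, where 140 of the 150 tested miRNAs matched a single locus and 123 of these overlapped another gene. The files name no genome build, so no coordinates are given. The slide, the scan and the position of each array were read from the scanner files. All arrays lay on 1 slide and came from 1 scan, with young arrays 1 and 2 and aged arrays 1 and 2 in the first row of the slide and young array 3 and aged array 3 in the second.

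Alternatives were the 75th percentile over all probes, quantile normalization, no scaling, normexp background correction with an offset of 50, the mean of all probes, Agilent's total signal per miRNA and the series matrix values. Further alternatives were 3 other filters on dim miRNAs, a higher floor, outlier spots kept, the replicate number or the slide row as a block, an intensity trend, array weights, other thresholds, other set tests, other definitions of detection and each array left out in turn. Scaling to the 4 spike-ins and a fit of the first slide row alone were added after the data were seen. The procedure was tested on simulated data for 224 miRNAs on 3 against 3 arrays. Each miRNA was drawn independently with the same SD, the observed median of 0.329. The procedure called 3 of 10 miRNAs simulated with a log2 fold of 1, 6 of 7 with 2, 11 of 11 with 3, 17 of 19 with 4 and 5 of 177 left unchanged. In a second simulation with an SD of 0.25 it called 8 of 181 left unchanged. Unchanged miRNAs made up a larger share of the calls than 0.05 in both simulations. Observed aged SDs were 0.78 for miR-483-5p, 1.51 for miR-451a and 1.65 for miR-3960, so these rates do not hold for miRNAs of wider spread. The number of arrays limits the precision.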

Results

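The miRNA content of bone-derived EVs, small membrane vesicles released by cells, was profiled in young mice of 1 month (n = 3 arrays) and aged mice of 16 months (n = 3 arrays). The comparison asked which miRNAs are enriched in EVs of aged bone relative to young bone. Of the 1881 mouse miRNAs on the array, 94 were detected on all 6 arrays, 278 on at least 1 and 1603 on none. The number detected was 113, 153 and 184 on young arrays 1 to 3 and 167, 198 and 235 on aged arrays 1 to 3, between 6.01% and 12.5% of the miRNAs. The unscaled 75th percentile of the probes detected on all arrays was 113, 140 and 191 scanner units on the young arrays and 146, 259 and 386 on the aged arrays. The 4 spike-in controls, RNAs of known amount added during labelling and hybridization, differed between the groups by a log2 value of 0.06 (SE 0.10, exact two-sided permutation p = 0.5).

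**Figure D1:**
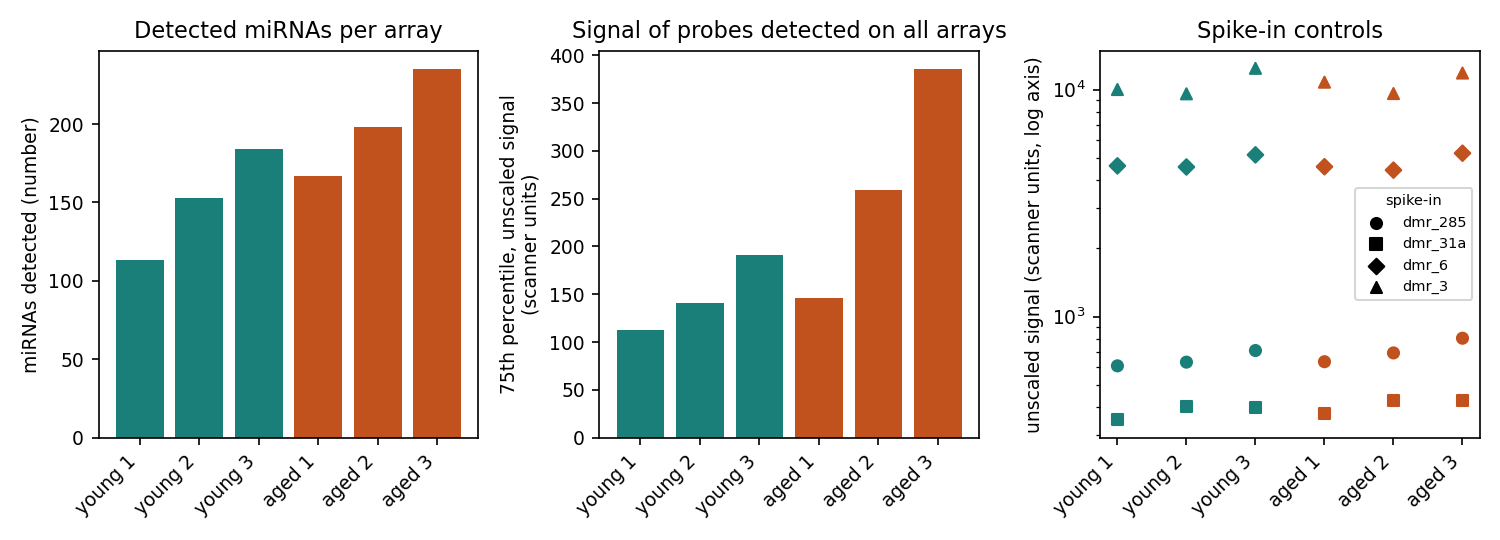
Number of detected miRNAs, 75th percentile of the unscaled signal (scanner units) of probes detected on all arrays and unscaled signal of the 4 spike-in controls (scanner units, log axis) on each of the 3 young and 3 aged arrays. Detected miRNAs ranged from 113 on young array 1 to 235 on aged array 3, while the spike-ins differed less between arrays.

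EVs of aged bone gave 200 ± 34.0 detected miRNAs (mean ± SD, n = 3) and EVs of young bone 150 ± 35.6, a difference of 50. In an exact two-sided permutation test the difference had p = 0.2, where the smallest p of the design is 0.1. All 3 aged arrays detected 140 miRNAs and all 3 young arrays 104. miR-483-5p, miR-5128, miR-6368, miR-2861 and miR-6973b-5p were among 13 miRNAs detected on all 3 aged arrays and on no young array, and 0 miRNAs showed the opposite pattern. The log2 bounds of the 13 ran from 2.26 for miR-5128 down to -0.08 for miR-7088-5p, the latter chosen after its values were seen. Detection was called before scaling, where the 75th percentile was on average 1.78-fold higher on the aged arrays. The pattern was not separated from this brightness. Without young array 1 the difference in detected miRNAs was 32, and without aged array 3 it was 32.5.

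miR-7118-5p, encoded within the plexin gene Plxnb2, rose in EVs of aged bone, and all 3 aged arrays lay above all 3 young arrays. Its log2 signal was 9.07 ± 0.87 in aged and 5.48 ± 0.65 in young EVs (mean ± SD, n = 3), where 2 of the 3 young arrays detected it. The log2 difference was 3.58 (SE 0.52, 95% confidence interval 2.35 to 4.82, limma Benjamini-Hochberg adjusted p = 0.0415), and its probes gave 3.58 and 3.51. It was the only miRNA of the 150 tested with a higher level that passed the threshold. At an unadjusted p under 0.05 limma gave 19 higher and 4 lower miRNAs. The groups did not overlap for 17 miRNAs with higher and 16 with lower values in aged EVs, 22% of those tested. The share for unfiltered values without a group difference is 10%. It is no exact reference here, as the detection rule used the groups and miRNAs are not independent.

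miR-483-5p, which lies within the imprinted growth factor gene Igf2, was detected on all 3 aged arrays and no young array. It was at least 4.70-fold higher in aged EVs, short of the threshold (limma Benjamini-Hochberg adjusted p = 0.0508). Over the alternatives other than the filters on dim miRNAs this adjusted p ranged from 3.61e-07 to 0.463. Its computed log2 difference, which the floor sets in part, ran from 0.80 with normexp and 1.55 with total gene signal to 2.88 without scaling. Its 4 probes gave 2.33, 2.31, 2.19 and 1.15, against the floor of the young arrays. Its measured log2 mean was 6.68 ± 0.78 in aged EVs against a floor of 4.36 on all 3 young arrays. miR-1897-5p, within the long non-coding RNA Sox2ot, had a log2 difference of 2.23 (SE 0.43), with 1 of 3 young arrays detecting it. The difference was 1.86 (SE 0.41) for miR-1224-5p, a mirtron of Vwa5b2, and 2.01 (SE 0.46) for miR-7011-5p, within Sema4a, which 1 young array detected. These 3 miRNAs had limma Benjamini-Hochberg adjusted p values of 0.0751, 0.107 and 0.107, and each was higher on every aged array than on any young array. miR-5128, within Strbp, was at least 4.79-fold higher (adjusted p = 0.215 by limma with Benjamini-Hochberg adjustment). Its computed difference against the floor ran from 1.01 with normexp and 1.18 with the mean of all probes to 3.09 without aged array 3. In the first slide row the difference was 3.04 and in the second 0.49. The bounds were at least 2.81-fold for miR-6368 (limma, Benjamini-Hochberg adjusted p = 0.143) and at least 2.38-fold for miR-6973b-5p within Gfra4 (0.286), whose aged array 3 value lay at the floor. For miR-6973b-5p the bound holds for the chosen probe only, as the computed log2 difference was 1.34 with that probe and 0.67 with the mean of all probes. These bounds hold for the floor and scaling chosen first, and the computed log2 differences were smaller with the highest floor (1.27 for miR-6368 and 1.13 for miR-6973b-5p). With normexp, whose offset compresses dim signals, they were 0.45 for both, 0.81 for miR-1897-5p and 0.68 for miR-7011-5p, and that of miR-1224-5p was 0.89 after quantile normalization.

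**Figure D2:**
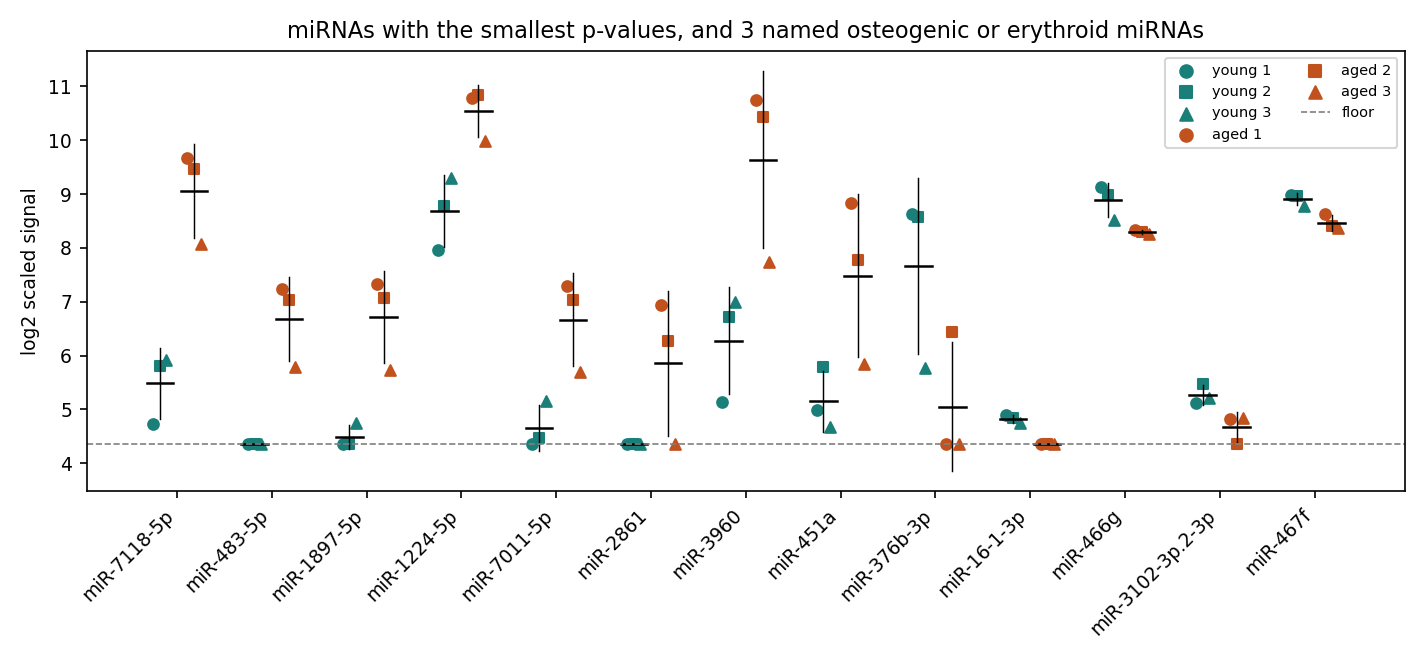
Log2 scaled signal of 13 miRNAs on the 3 young and 3 aged arrays, with group means as horizontal bars, SD as vertical lines and the floor of 4.36 as a dashed line. miR-7118-5p lay at 4.73 to 5.91 on the young and 8.07 to 9.67 on the aged arrays, and aged array 3 was the lowest aged array for each of the 8 miRNAs with higher aged means.

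The call of miR-7118-5p was lost without young array 1 (adjusted p = 0.191), young array 2 (0.0851), aged array 1 (0.199) or aged array 2 (0.337), and held without young array 3 (0.0438) and aged array 3 (0.00122), all by limma with Benjamini-Hochberg adjustment. With total gene signal its adjusted p was 0.0547 and miR-5128 passed in its place (log2 difference 2.86 against the floor, adjusted p = 0.0211, limma, Benjamini-Hochberg). Over the alternatives other than the filters on dim miRNAs the limma Benjamini-Hochberg adjusted p of miR-7118-5p ranged from 5.99e-15 to 0.337. With the slide row as a block its adjusted p was 0.0548 by limma with Benjamini-Hochberg adjustment, and the log2 difference was 4.30 in the first row of the slide and 2.15 in the second.

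No miRNA passed the threshold with a lower level in aged EVs by limma, and 4 did at an unadjusted p under 0.05. The largest negative difference was that of miR-376b-3p, a member of the imprinted Dlk1-Dio3 cluster, with a log2 difference of -2.61 (SE 0.92, limma Benjamini-Hochberg adjusted p = 0.245), between -3.42 without young array 3 and -1.42 with normexp, and -2.16 without aged array 3. It was detected on all 3 young and 2 of 3 aged arrays, and it was lower on 2 of the 3 aged arrays than on any young array. Differences were smaller for miR-16-1-3p (-0.47, SE 0.18), encoded in Dleu2 and detected on 1 aged array, and for miR-3102-3p.2-3p (-0.60, SE 0.23), both at a limma Benjamini-Hochberg adjusted p of 0.276. miR-466g (-0.59, SE 0.23) and miR-467f (-0.45, SE 0.19) had limma Benjamini-Hochberg adjusted p values of 0.276 and 0.286. All 3 aged arrays lay below all 3 young arrays for these 4 miRNAs. Without scaling between arrays the differences were 0.01 for miR-16-1-3p, 0.13 for miR-3102-3p.2-3p, 0.17 for miR-466g and 0.31 for miR-467f, while the median of all tested miRNAs was 0.66. Without young array 1 the number of lower miRNAs was 1 and without young array 3 it was 7, against 0 with all arrays.

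Of the miRNAs known to promote osteogenesis, miR-3960 and miR-2861 were tested, which are known to promote osteoblast differentiation. miR-3960 had a log2 difference of 3.36 (SE 0.88, limma Benjamini-Hochberg adjusted p = 0.132) and was higher on all 3 aged arrays than on any young array. miR-2861 was at least 2.42-fold higher (limma Benjamini-Hochberg adjusted p = 0.286), being detected on all 3 aged arrays and no young array. Both passed when adjusted over the list alone, and neither over all 150 tested miRNAs. The list held 14 miRNAs on the array. miR-2861 and miR-483-5p are known to have been followed up by the study, whose samples these are, so their results are not independent evidence. The aged array 3 value of miR-2861 lay at the floor, as did its 3 young values, and its computed log2 difference was 0.54 with normexp, below the bound. That of miR-3960 ran from 2.49 with normexp to 4.66 in the first slide row. In the second row of the slide the log2 difference of miR-3960 was 0.76. Of the 16 miRNAs known to inhibit osteogenesis, miR-125b-5p (0.35, SE 0.36) and miR-211-5p (-0.38, SE 0.31) were tested and 0 passed, with limma Benjamini-Hochberg adjusted p values of 0.664 and 0.553 and 0 adjusted over the list alone. Their signs turned under other settings, to -0.94 with total gene signal for miR-125b-5p and to 0.32 without scaling and 0.29 with spike-in scaling for miR-211-5p. miR-21a-5p, encoded in Vmp1, was the tested member of the adipogenesis list and, with miR-22-3p, of the senescence list. Their log2 differences of 0.21 (SE 0.79) and 0.02 (SE 0.54) did not pass, over all tested miRNAs or adjusted over the list alone, and that of miR-22-3p was -0.33 after quantile normalization, -0.05 with normexp and -1.14 with total gene signal.

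Of the markers of blood cells, miR-451a, which is abundant in erythroid cells, had a log2 difference of 2.34 (SE 0.74, limma Benjamini-Hochberg adjusted p = 0.215), higher on all 3 aged arrays than on any young array. miR-92a-3p, on the erythroid list and the tested member of the list of the miR-17 to miR-92a cluster and its paralogs, differed by -0.05 (SE 0.67), with a sign that turned with the 75th percentile over all probes (0.15), without scaling (0.62), with spike-in scaling (0.56) and with normexp (0.02). Adjusted over the list alone 1 of these 2 erythroid miRNAs, miR-451a, passed, and 0 over all tested, and 0 passed for the list of the miR-17 to miR-92a cluster and its paralogs. With normexp miR-451a differed by 1.13, and miR-92a-3p ranged from -2.03 with total gene signal to 0.77 without aged array 3. By slide row miR-451a differed by 2.91 and 1.18, and miR-92a-3p by 0.74 and -1.62. Only 3 of the 8 erythroid miRNAs on the array were detected on any array. The erythroid miRNAs miR-144-3p and miR-144-5p, chosen after their values were seen, were detected on none. The myeloid miRNA miR-223-3p was detected on 1 young and 2 aged arrays and was not tested, and 2 of the 8 myeloid miRNAs on the array were detected on any array. Of the lymphoid, endothelial, muscle, cartilage, liver, neural, epithelial and fibroblast or mesenchymal lists, and of the miR-30 family, 0 members were detected on any array. In the miR-23a cluster and the miR-29 family, 1 member each was detected on some arrays, miR-23a-3p and miR-29a-3p, and 0 were tested. let-7i-5p (-0.61, SE 0.33) and let-7b-5p (-0.41, SE 0.36) were the tested let-7 members, and 0 passed over all tested or adjusted over the list alone. Both turned positive without scaling (0.15 and 0.31) and with spike-in scaling (0.10 and 0.25).

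Among regional clusters, the Sfmbt2 cluster, a large imprinted block of rodent miRNAs, had 12 of its 14 tested members negative, a median of -0.21 and a mean of -0.22. Of all 150 tested miRNAs 81 were negative, and of the 80 tested miRNAs named 3p 54 were. Examples are miR-466g (-0.59), miR-466f-3p (-0.49, SE 0.22), miR-466h-3p (-0.44, SE 0.19) and miR-466i-3p (-0.44, SE 0.20), of which 0 passed over all tested miRNAs or adjusted over the list alone. camera with its preset correlation of 0.01 gave an adjusted p = 0.0115 (limma, Benjamini-Hochberg), with a range of 2.01e-27 to 0.410 over the other settings. The estimated correlation was 0.342, far above the preset, and with it the adjusted p of camera was 0.492. By fry it was 0.243, so a shift of the cluster rests on the preset correlation. The median stayed negative with quantile normalization (-0.25), normexp (-0.16) and total gene signal (-0.36) and turned positive with the 75th percentile over all probes (0.05), without scaling (0.52) and with spike-in scaling (0.47). Under those last 3 scalings the camera direction was still lower, unlike the median. They moved the median of all tested miRNAs by 0.26, 0.71 and 0.65. By the reference, 8 of the 14 lay in Sfmbt2, 3 at other genes, such as miR-466i-3p in Cdk13, and 3 matched no single locus. Of all 23 tested miRNAs lying in Sfmbt2 by the reference, counted after the values were seen, 20 were negative and 3 positive, with a median of -0.16. The camera adjusted p (limma, Benjamini-Hochberg) was 0.410 without young array 1 and 0.0857 without aged array 1.

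The miRNAs numbered from 1900, added late to miRBase and often less well characterised, lay higher in aged EVs by camera with its preset correlation (limma, Benjamini-Hochberg adjusted p = 0.00595). With the estimated correlation of 0.319, far above the preset, the adjusted p of camera was 0.492. The 4 members with the smallest p-values were miR-7118-5p, miR-7011-5p, miR-6931-5p and miR-3960, of which miR-6931-5p had a log2 difference of 2.14 (SE 0.55, limma Benjamini-Hochberg adjusted p = 0.132). Of the 78 tested, 45 were positive and 33 negative, with a median of 0.08 and a mean of 0.44, and 1 passed over all tested and 1 adjusted over the list alone. The adjusted p of the list was 0.395 by fry and 0.000600 to 0.782 over the other settings of camera (limma, Benjamini-Hochberg). The median turned negative with normexp (-0.10), with total gene signal (-0.03) and among miRNAs detected on all 6 arrays (-0.07), where the camera direction was still higher, and the adjusted p was 0.410 without young array 1 (limma, Benjamini-Hochberg). In the Igf2 and H19 region miR-483-5p stood apart from miR-483-3p (-0.13, SE 0.22) and miR-675-3p (0.01, SE 0.37), of which 2 of 3 young arrays detected the latter. The list of 3 did not pass (camera, limma, Benjamini-Hochberg adjusted p = 0.301), 1 member passed adjusted over the list alone and 0 over all tested, and its median was 0.01, its mean 0.74 and its camera direction higher. miR-483-3p was positive with the 75th percentile over all probes (0.15), without scaling (0.63) and with spike-in scaling (0.57). miR-376b-3p was the tested member among the 53 miRNAs of the fixed Dlk1-Dio3 list on the array, so that its p adjusted over the list alone was its unadjusted limma p of 0.0265, before any Benjamini-Hochberg adjustment, and 0 passed over all tested. That list left out 3 tested miRNAs which lie between Dlk1 and Dio3 by the reference, chosen after their values were seen. These were miR-3072-5p (1.62, SE 0.58), miR-1188-3p (-0.19, SE 0.20) and miR-485-3p (-0.05, SE 0.25), and 0 passed.

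The 10 miRNAs with the highest mean signal, a ranking of probe signals and not of amounts, included miR-8110, with a log2 difference of 1.62 (SE 0.52, limma Benjamini-Hochberg adjusted p = 0.215), and miR-1224-5p and miR-6931-5p. The other 7 had negative differences and did not pass, among them miR-669p-3p (-0.41, SE 0.19), miR-877-3p (-0.30, SE 0.20), a mirtron of Abcf1, and miR-466i-5p (-0.32, SE 0.28). These 7, which also held miR-466f-3p, miR-466g, miR-466i-3p and miR-467f, all turned positive without scaling (0.17 to 0.46) and with spike-in scaling (0.11 to 0.40), settings that raised the median of all tested miRNAs to 0.66 and 0.60. The difference of miR-8110 was 0.66 after quantile normalization. Differences within the first row of the slide were 2.37 for miR-8110 and 2.44 for miR-1224-5p, and 0.11 and 0.68 in the second.

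The authors' deposited list named 37 miRNAs as higher and 9 as lower in aged EVs, led by miR-483-5p at 14.5-fold, miR-2861 at 12.2-fold, miR-7118-5p at 8.89-fold and miR-1897-5p at 8.69-fold. Its lower miRNAs included let-7i-5p at a ratio of 0.568 and let-7d-3p at 0.662 in the authors' deposited list, the latter chosen after its values were seen. Of the 46 miRNAs of the authors' deposited list, 40 had the listed direction here, 6 had equal floored values and 0 the opposite direction, with 37 to 45 in the listed direction over the alternatives. The authors' deposited list was chosen on these samples, so this count is not independent evidence. Of its 46 miRNAs, 27 met the detection rule here, 17 of them had an unadjusted p under 0.05 by limma and 1, miR-7118-5p, passed after Benjamini-Hochberg adjustment. The log2 fold changes of the authors' deposited list and those computed here had a Pearson r of 0.846 across these 27 miRNAs, which are not independent replicates. p-values in the authors' deposited list ran from 0.000204 to 0.0487. If they are unadjusted, the smallest becomes 0.383 when multiplied by the 1881 miRNAs of the array. This is no full Benjamini-Hochberg adjustment, as p-values of miRNAs outside the list are not known. The list held no higher miRNA below 1.51-fold and no lower one above a ratio of 0.662. Whether the listed miRNAs pass an adjustment thus cannot be told.

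**Figure D3:**
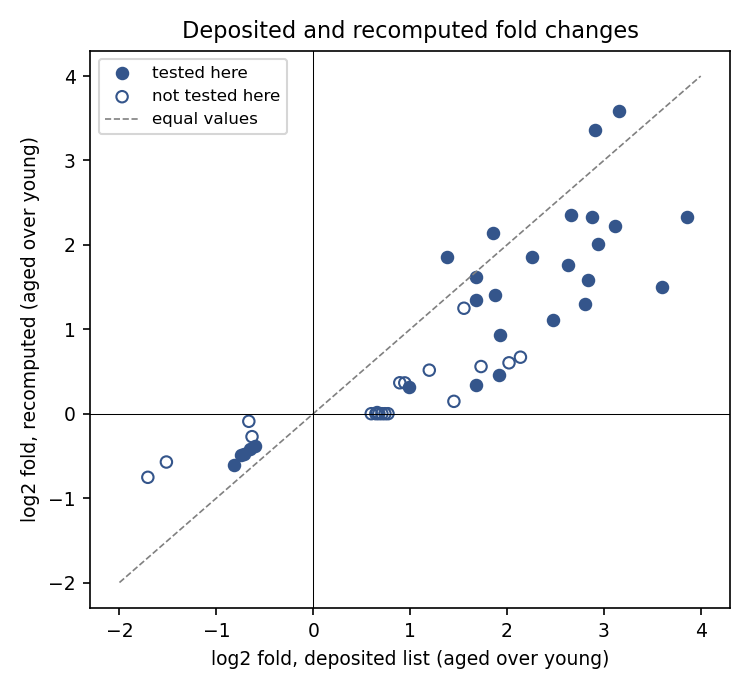
Log2 fold change (aged over young) of the 46 miRNAs of the authors' deposited list (horizontal axis) against the value computed here (vertical axis), with filled points for the 27 tested here and a dashed line of equal values. No miRNA had opposite signs, and 6 lay at 0 on the vertical axis because both groups were at the floor.

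The number of miRNAs passing the threshold depended on aged array 3, whose signals lay nearer the young arrays than those of aged arrays 1 and 2. The scaled profile of aged array 3 correlated with young array 3 at r = 0.92 and with aged arrays 1 and 2 at 0.77 and 0.81, across miRNAs, which are not independent replicates. Without it the detection rule kept 174 miRNAs against 150, and limma with Benjamini-Hochberg adjustment gave 41 higher and 0 lower miRNAs. Some of the 41 were thus not among the 150. Among the 41 were miR-7118-5p, miR-3960 and miR-451a, the last 2 with log2 differences of 4.31 and 3.15, and also miR-483-5p and miR-2861, which no young array detected. The adjusted p values of miR-3960, miR-451a, miR-483-5p and miR-2861 by limma with Benjamini-Hochberg adjustment were 0.00286, 0.00362, 0.000435 and 0.00186. Over the alternatives other than the filters on dim miRNAs they ranged from 5.32e-14 to 0.553, 5.12e-08 to 0.608, 3.61e-07 to 0.463 and 0.00109 to 0.608. Leaving out young arrays 1, 2 or 3 gave 0, 0 and 1 higher miRNAs, and leaving out aged arrays 1 or 2 gave 0 each. The number of higher miRNAs was also 18 with the 75th percentile over all probes, 29 without scaling and 33 with spike-in scaling, against 1. The last 2 came from fits with 600 degrees of freedom against 6.69, so their counts are not from fits of like form.

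**Figure D4:**
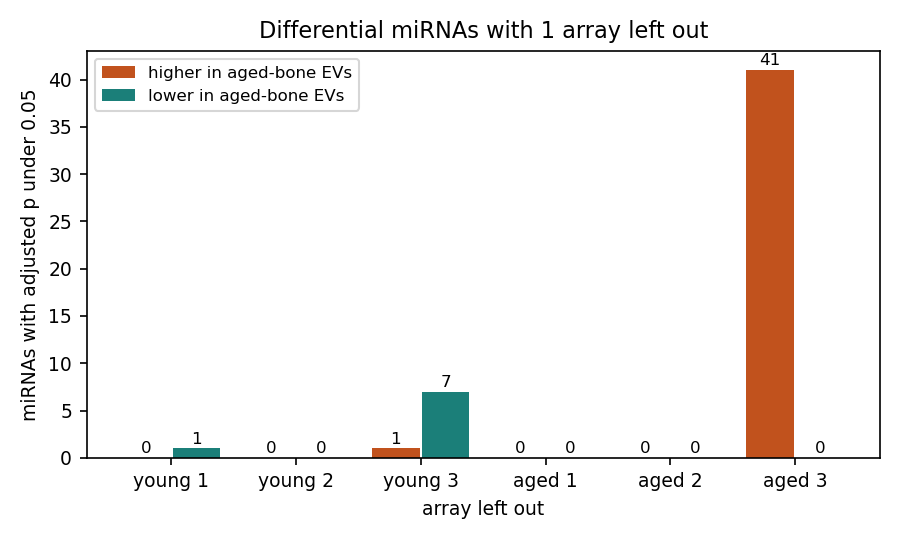
Number of miRNAs with an adjusted p under 0.05 (limma, Benjamini-Hochberg) that were higher or lower in EVs of aged bone when 1 of the 6 arrays was left out. The number of higher miRNAs was 41 without aged array 3 and at most 1 without any other array, and the number of lower miRNAs reached 7 without young array 3. The number tested also changed, from 150 without young array 2 to 174 without aged array 3.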

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

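The spike-in and sample-label tests, the splits of the arrays, the spike-in scaling and the fit of the first slide row were chosen after the result was seen, while the mixture test was set before its own result was seen.

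Probes on the aged arrays were brighter, with a median log2 difference of 0.88 for the probes detected on all arrays (exact two-sided permutation p = 0.2, smallest possible 0.1). Lower efficiency of labelling, hybridization or scanning on the young arrays did not account for this, since the 4 spike-ins differed by a log2 value of 0.055 (SE 0.0952). A difference in RNA amount, vesicle yield or amplification, or age itself, may underlie it, and the spike-ins do not cover steps before their addition. Scaling to the spike-ins, which keeps the difference, gave 33 higher and 2 lower miRNAs. RNA quantities before labelling, not used here, would bear on the RNA amount but would not separate all of these.

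Of 8 control probe sets outside the miRNA analysis, hur_2 and hur_4 were brighter on every aged array than on any young array, and they were chosen after their values were seen. The lowest p of the others was 0.1 for hur_5, which was dimmer on the aged arrays but had at most 1.36 scanner units on any array, and the remaining sets had exact permutation p values of 0.2 to 1. For hur_2 the lowest aged array had 325 scanner units and the highest young array 263, and for hur_4 these were 45.4 and 20.3 (exact two-sided permutation p = 0.1 each, the smallest possible). After scaling by the 75th percentile the lowest aged value was below the highest young value for both, at 0.844 against 1.87 for hur_2. Their targets are not given in the sources used here.

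Aged array 3 lay nearer the young arrays than aged arrays 1 and 2 did, with a first principal component of -1.68 against 10.3 and 7.44. Position in the second slide row stays open, as that row held 1 array of each group. The mean log2 spike-in signal was 11.01 on young array 3 and 11.07 on aged array 3, against 10.79 to 10.88 on the arrays of the first row. Young array 3 and aged array 3 had the highest correlation of any young and aged pair (r = 0.92 across miRNAs). Their deviations from the group means correlated at -0.200 (95% bootstrap interval -0.405 to -0.0572), which with 1 array of each group does not decide on an effect of the row. The bootstrap intervals of this paragraph resampled miRNAs, which are not independent replicates, and do not measure variation between samples. A young sample under an aged label could not be separated from a true aged sample, as its slope along the difference of the other aged arrays exceeded the highest young slope by 0.00494 (95% bootstrap interval -0.127 to 0.112). A mixture of young and aged material predicts fewer miRNAs outside the range of the other 5 arrays than the 33.3% expected by chance, and 34 of 89 were found, 38.2% (27.6 to 48.1), which neither favours nor excludes a mixture. A true aged sample with a young-like profile remains possible. A repeat of the same sample would bear on the slide row and would not separate the other explanations.

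The 10 splits of the arrays into 3 against 3 cannot give a share under 0.05. For higher miRNAs 1 of 10 splits, the real grouping, reached the real count of 1, with 0 as the highest other count. For lists 6 of 10 splits reached the real count of 2, with 2 as the highest other.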

How the results depend on the processing

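With 3 arrays per group, all on 1 slide, the results depended on scaling and on single arrays, and the cause was not tested except where named. Of 758 alternative values of named miRNAs and lists, each counted once, 592 kept their sign and their side of the threshold, whatever their size. With the sign kept, 81 newly passed and 16 no longer passed. The other 69 changed sign, whether or not they also changed their side of the threshold. Of the sign changes, 16 came without scaling and 15 with scaling to the spike-ins, which by construction shift miRNAs largely alike and say little about single miRNAs. With all arrays and the first choice of settings, 1 miRNA was higher, 0 were lower and 2 lists were shifted, the latter with the preset correlation of camera alone, as 0 were with an estimated correlation (adjusted p = 0.492 each by limma with Benjamini-Hochberg adjustment) and 0 with fry.

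The number of higher miRNAs was 18 with the 75th percentile over all probes, 5 with quantile normalization, 29 without scaling, 33 with scaling to the spike-ins, 26 with array weights, 42 in slide row 1 only and 19 with unadjusted p and a 2-fold change. It was 0 with the mean of all probes, no filter on dim miRNAs, detection on all 6 arrays, detection on at least 1 array, the highest floor, outlier spots kept, the slide row block and the replicate block. The deviations of young 1 and aged 1, young 2 and aged 2 and young 3 and aged 3 correlated at -0.48, 0.32 and -0.20 across miRNAs. With 3 arrays per group these mixed signs do not settle whether replicates with the same number were paired. The replicate block gave 0 higher and 0 lower miRNAs, with 5.06 degrees of freedom against 6.69. The number of lower miRNAs was 2 without scaling, 2 with scaling to the spike-ins, 1 with array weights, 1 with detection on at least 1 array, 11 in slide row 1 only and 1 with unadjusted p and a 2-fold change. The number of shifted lists was 0 without scaling, 0 with scaling to the spike-ins, 0 with an estimated correlation, 0 with fry, 1 with no filter and 1 with detection on at least 1 array.

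Signs turned as follows, as log2 differences. Without scaling, where by construction the brighter aged arrays raise the values, they were 0.0115 for miR-16-1-3p, 0.17 for miR-466g, 0.13 for miR-3102-3p.2-3p, 0.31 for miR-467f, 0.62 for miR-92a-3p, 0.32 for miR-211-5p, 0.15 for let-7i-5p, 0.31 for let-7b-5p, 0.63 for miR-483-3p, 0.32 for miR-466h-3p, 0.27 for miR-466f-3p, 0.32 for miR-466i-3p, 0.43 for miR-466i-5p, 0.46 for miR-877-3p, 0.35 for miR-669p-3p and 0.52 for the Sfmbt2 median. Scaling to the spike-ins, for the same reason, gave in that order without miR-16-1-3p 0.11, 0.0740, 0.26, 0.56, 0.29, 0.10, 0.25, 0.57, 0.26, 0.21, 0.27, 0.38, 0.40, 0.29 and 0.47. The 75th percentile over all probes gave 0.15 for miR-92a-3p, 0.15 for miR-483-3p and 0.0504 for the Sfmbt2 median. Quantile normalization gave -0.33 for miR-22-3p. Normexp gave 0.0161 for miR-92a-3p, -0.0531 for miR-22-3p, -0.0855 for miR-675-3p and for the Igf2 and H19 median and -0.10 for the median of miRNAs numbered from 1900. The mean of all probes gave -0.0385 for miR-675-3p and for the Igf2 and H19 median. Total gene signal gave 0.34 for miR-16-1-3p, -0.94 for miR-125b-5p, -1.14 for miR-22-3p, -3.40 for miR-675-3p, -0.16 for the Igf2 and H19 median and -0.0314 for the median of miRNAs numbered from 1900. The latter was -0.0681 with detection on all 6 arrays. miR-92a-3p was 0.0564 with the highest floor, 0.34 with array weights and 0.74 in slide row 1 only, and miR-675-3p was -0.25 with array weights.

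With each array left out in turn the number of higher miRNAs ranged from 0 to 41, that of lower miRNAs from 0 to 7 and that of shifted lists from 0 to 2. The log2 difference ranged from -0.0546 to 0.66 for miR-125b-5p, -0.39 to 1.1 for miR-21a-5p, -0.58 to 0.63 for miR-22-3p, -0.47 to 0.31 for miR-675-3p and -0.72 to 0.77 for miR-92a-3p. The median ranged from -0.26 to 0.31 for the Igf2 and H19 list and from -0.20 to 0.23 for the miRNAs numbered from 1900.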

Other observations

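The common-factor test of the hairpin arms was chosen after the result was seen, while the count of hairpins over the splits was set before its own result was seen.

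A miRNA hairpin can release a miRNA from its 5p arm and another from its 3p arm, and for 4 of the 12 hairpins with both arms tested the arms differed in their change with age (limma, Benjamini-Hochberg adjusted). The log2 difference was 3.58 for miR-7118-5p and -0.12 for miR-7118-3p, and at least 2.23 for miR-483-5p, which no young array detected, and -0.13 for miR-483-3p. It was 2.01 for miR-7011-5p and -0.07 for miR-7011-3p, and -0.38 for miR-211-5p and 1.86 for miR-211-3p. The adjusted p of the arm differences (limma, Benjamini-Hochberg, n = 3 per group) was 0.000563 for miR-7118, 0.000763 for miR-483 and miR-211 and 0.00327 for miR-7011, and for miR-483 it ranged from 7.02e-11 to 0.477 over the settings and rests on floored young values of the 5p arm. miR-7118-3p, miR-7011-3p and miR-211-3p were chosen after their values were seen.

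A single common factor for every miRNA, such as a scaling of an array, moves both arms alike only where both lie above the floor. That held on every array for miR-7118, so a common factor does not account for its unequal arms. miR-483-5p lay at the floor on all 3 young arrays, and miR-7011-5p and miR-211-3p on young array 1, so a factor need not cancel for these hairpins. The count of 4 restates the pattern that prompted the test. Arm choice in the cells, sorting of single arms into vesicles or cross-hybridization of a probe may each underlie the difference, none was tested, and quantitative PCR of both arms would bear on the last. Total gene signal gave 1 such hairpin and the filter on all 6 arrays 0 of 6, a filter that itself removes the 4 hairpins. Over the splits of the arrays into 3 against 3, 1 of 10 reached the real count of 4, with 1 as the highest other count, and 10 splits cannot give a share under 0.05.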
